A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

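The series measured RNA from Saccharomyces cerevisiae with Affymetrix Yeast Genome S98 arrays, 15 arrays in 5 groups of 3. All strains were of the BY4741 background and expressed a fragment of human huntingtin (Htt) from a galactose promoter, with either 25 glutamines (Htt25Q) or 103 glutamines (Htt103Q). Per the labels, cells grew at 30 °C in 12 mL of synthetic medium without uracil and with 2% galactose, from an optical density of 0.2 to about 1, and total RNA was released with glass beads and purified on columns before biotin labelling. The groups were Htt25Q, Htt103Q, and strains deleted for BNA4, MBF1 or UME1 that expressed Htt103Q.

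The deposited values were on a log2 scale, with 1 summarised intensity per probe set and array. The method of summary and normalization is not given in the sources used here. The table held 9335 probe sets. The 60 control probe sets were left out of the tests and used to check the arrays, which left 9275, of which 6504 matched 1 gene, 328 matched several genes and 2443 had no gene symbol. The genes with at least 1 probe set numbered 5656. Coordinates are those of the R64 assembly. The array holds no probe sets that could serve as a background from another yeast species, so the lowest deposited values served as the floor.

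The values fell into 2 processing sets, each with its own exact lowest value. The first set held the 9 arrays of Htt25Q, Htt103Q and the ume1 deletion, with a lowest value of 2.06 and array medians of 6.35 to 6.47. The second held the 6 arrays of the bna4 and mbf1 deletions, with a lowest value of 2.02 and array medians of 6.78 to 6.84. A comparison of the bna4 or mbf1 deletion with either control therefore compared strains and processing sets at once, and no fit can part them. A rule fixed before the data were examined switched the main values from the deposited ones to quantile normalized ones if array medians differed by more than 0.1, and they did. Quantile normalization removes any change in the overall distribution of signal, so every change is relative to the other probe sets of the array. All values below are quantile normalized unless called deposited. A group was treated as at the floor if its 3 arrays all lay within 0.1 of the lowest deposited value, and a fold change against such a group is a lower bound.

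The limma package (version 3.58.1, R 4.3.3) fitted 1 linear model with the 5 group means to all 15 arrays, with empirical Bayes moderation of the variance and two-sided tests. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Differences among the 3 deletion strains were tested with the moderated F test. Each comparison was also counted by the probe sets whose 3 arrays of a group all lay above or below the 3 of the other, which chance gives for 10% of probe sets. The labels do not state that replicates were separate cultures, so each p measures the spread between these samples. The number of arrays limits the precision, and replicate numbers did not pair the arrays across groups, with correlations of residuals of −0.169 to 0.434 between arrays of the same number.

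Gene lists fixed in advance covered translation, protein quality control, stress, mitochondria, metabolism, metal and phosphate regulons, cell wall, mating type, meiosis and cell cycle. A gene can belong to several lists. The 35 lists with at least 5 measured members were tested with camera from limma, which compares the members with all other genes, at a preset correlation of 0.01 and with adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether members move one way, were the alternatives. Members were called over all probe sets and also adjusted over the list alone.

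Genes were named by a rule. The deleted genes, URA3 and the galactose genes came first, in every group. Then came the 10 largest rises and 10 largest falls among called probe sets with 1 gene symbol and no overlap between the groups' arrays, leaving out the deleted gene, and up to 4 called members of each list with the largest change, or the pair with the smallest p where none was called. For changes in all 3 deletion strains the 10 with the largest mean change were taken, for genes apart in 1 strain 5 each, and for strains against Htt25Q the 5 largest rises and falls. The comparison of the mbf1 with the bna4 deletion, and its named genes by the same rule, was added after the processing sets were seen.

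Whether a deletion moved expression towards Htt25Q was measured by the covariance, across probe sets, of its log2 fold changes against Htt103Q with those of Htt103Q against Htt25Q. Both contrasts use the Htt103Q arrays, which alone gives a negative value, so 100 simulations with no effect and a split of the Htt103Q arrays gave the reference. Genes are not independent replicates, and no p is given for it.

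The procedure was tested on simulated data with 200 of 9275 probe sets changed between Htt103Q and Htt25Q. The changed probe sets were drawn from the brighter ones, so the recovery of dim probe sets was not tested. No difference between the processing sets was simulated. In the real data the bna4 and mbf1 deletions had 44.1% and 36.5% of probe sets called against Htt103Q. The false shares given below for these comparisons therefore do not carry over to the real ones. With equal spread in all groups, 4 of 118 calls were false, and 68.7% of changes of 1 and 18.2% of changes of 0.5 on the log2 scale were found. In the other comparisons simulated, 56.7% to 59.7% of changes of 1 were found. False calls were 11 of 120, 7 of 117 and 12 of 121 when the bna4, mbf1 and ume1 deletions were compared with Htt103Q in this way, and 12 of 119 for mbf1 against bna4, 10.1% where 5% is the target. With spread scaled by group, between Htt103Q and Htt25Q, 24 of 141 calls were false. With each probe set given its own standard deviation per group, taken from 3 arrays and so overstating unequal spread, 203 of 335 calls were false in the fit to all arrays and 58 of 158 in the fit to the first set alone. For the ume1 deletion against Htt103Q these were 89 of 208 and 22 of 108, and in the fit to all arrays 28 of 146 for bna4 and 46 of 159 for mbf1 against Htt103Q and 34 of 146 for mbf1 against bna4. The last model was the only 1 in the first run, and the other two were added after its result was seen.

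Alternatives chosen in advance were the deposited values, centring of each array on its median, a filter on dim probe sets (below 3.30, the 25th percentile, which kept 7328), control probe sets kept, 1 probe set per gene, only the groups compared in the fit, array weights, a trended and robust variance prior, a fold change of at least 1.5, replicate number as a block, and each array left out in turn. The dim filter was planned on probe sets of another yeast species, and the 25th percentile took their place because the table holds none. A fit to 1 processing set alone with deposited values, and a fit without Htt25Q array 1 and the ume1 deletion array 1, were added after seeing the data. Alternatives for values on a linear scale did not apply. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.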

Results

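RNA levels were measured with 15 arrays of 9335 probe sets in 5 groups of budding yeast, each of 3 arrays. A fragment of human huntingtin with 25 glutamines (Htt25Q), a length found in healthy people, served as the control for the aggregating fragment with 103 glutamines (Htt103Q). The other three groups expressed Htt103Q in strains without BNA4, MBF1 or UME1. BNA4 encodes kynurenine 3-monooxygenase of the pathway from tryptophan to NAD, MBF1 a coactivator that works with the transcription factor Gcn4, and UME1 a subunit of histone deacetylase complexes with Rpd3. Values are log2 signals, quantile normalized across arrays, and each group has n = 3. Array medians as deposited ranged from 6.35 to 6.47 in Htt25Q, Htt103Q and the ume1 deletion, and from 6.78 to 6.84 in the bna4 and mbf1 deletions, which formed a second processing set. The first principal component held 59.3% of the variance and parted the processing sets. It stood at −44.7 to −30.6 in the arrays of the first set and at 48.4 to 59.9 in those of the second.

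The deleted genes were low in their own strains. BNA4 (chromosome II, 39145 to 40527) had a signal of 6.99 ± 0.132 (SD, n = 3) in Htt25Q, 6.69 ± 0.169 in Htt103Q, 7.84 ± 0.116 in the mbf1 deletion and 2.12 ± 0.134 in the bna4 deletion. In the ume1 deletion it had 5.14 ± 0.193. MBF1 (chromosome XV, 877230 to 877685) stood at 10.3 ± 0.254 in Htt25Q, 11.4 ± 0.141 in Htt103Q, 10.5 ± 0.142 in the bna4 deletion, 11.6 ± 0.149 in the ume1 deletion and 2.09 ± 0.0342 in the mbf1 deletion. UME1 (chromosome XVI, 289669 to 291051) stood between 6.88 and 7.05 in 4 groups and at 2.34 ± 0.305 in the ume1 deletion. Against Htt103Q, the log2 fold change in the gene's own deletion was at least −4.57 for BNA4 (adjusted p = 3.0e-10) and at least −9.33 for MBF1 (1.26e-12), both close to the floor, and −4.54 for UME1 (8.71e-09). The marker URA3 had means of 10.1 in Htt25Q, with an SD of 1.35, 8.9 in Htt103Q, 9.1 in bna4, 10.3 in mbf1 and 9.21 in the ume1 deletion. GAL1, GAL2, GAL7 and GAL10, which the galactose medium induces, had means between 12.2 and 13.2 in all groups and were not called between Htt103Q and Htt25Q or between the ume1 deletion and Htt103Q. The regulator GAL4 fell in the bna4 (−1.14) and mbf1 (−1.13) deletions against Htt103Q, across the processing sets, with values up to −0.38 and −0.31 among the alternatives and adjusted p up to 0.0762 in the second. GAL2 fell by 0.36 in the mbf1 deletion (0.0221), with adjusted p up to 0.0902 among the alternatives. Of the genes next to the deleted ones, BRN1 (chromosome II, 40831 to 43095) rose by 0.30 in the bna4 deletion (adjusted p = 3.74e-05), and 1 of the probe sets of BUD7 had −0.24 in the mbf1 deletion (0.0272) while its others were not called.

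**Figure D1:**
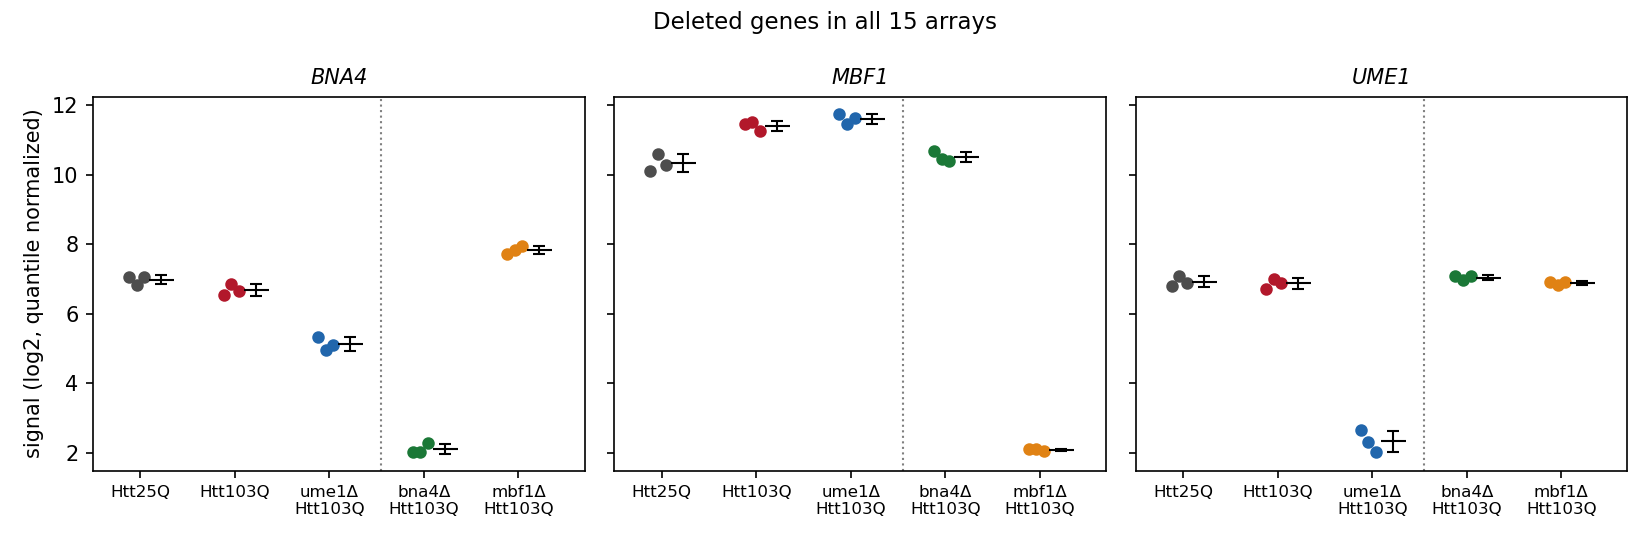
Log2 signal of BNA4, MBF1 and UME1 (vertical axis) in the 15 arrays by group, with points for arrays, bars for the mean ± SD of 3 arrays and a dotted line between the processing sets. The mean of each gene in its own deletion lies between 2.09 and 2.34, and BNA4 has a mean of 5.14 in the ume1 deletion.

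The array controls set some samples apart. Htt25Q array 1 had an actin signal 2.48 higher on the log2 scale at the 3' than at the 5' end, against −0.33 to 0.31 in the other 14 arrays, a sign of degraded RNA. Signal of the 18S ribosomal RNA controls was 10.4 in the ume1 deletion array 1 and 5.15 to 7.28 in the other 8 arrays of the first set, against 11.1 to 11.2 in the bna4 and 9.53 to 10.7 in the mbf1 deletion. The median SD between replicates was 0.248 in Htt25Q, 0.130 in Htt103Q, 0.0864 in bna4, 0.137 in mbf1 and 0.177 in ume1.

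**Figure D2:**
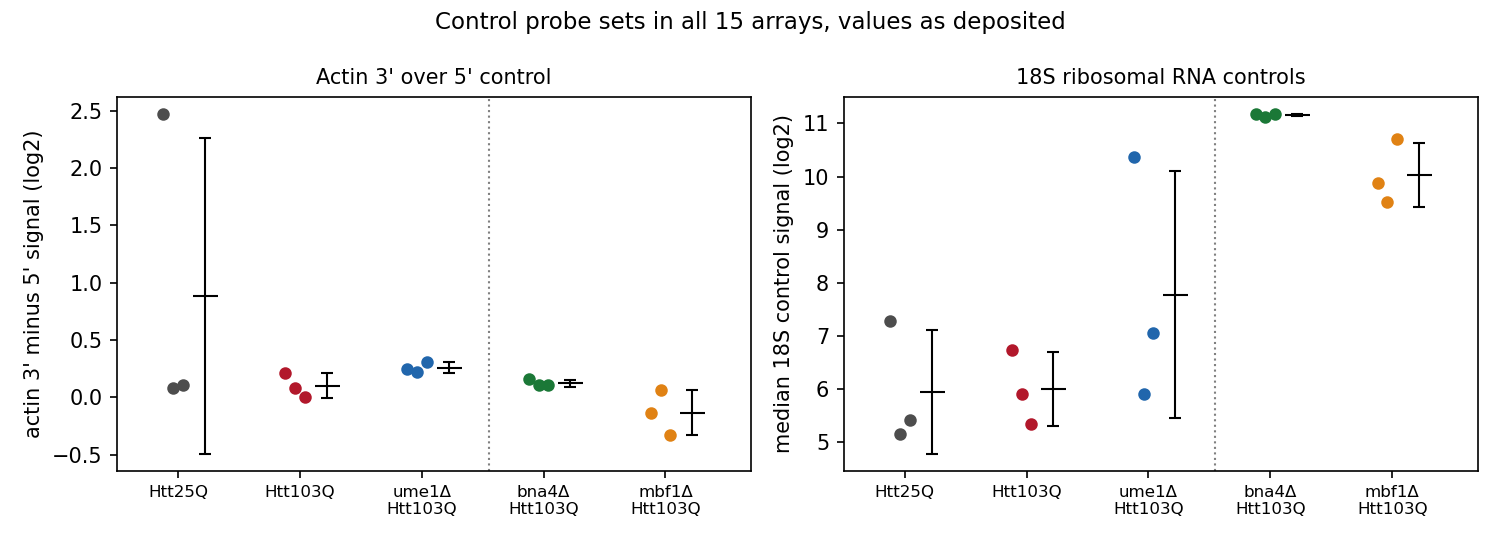
Actin 3' minus 5' signal and the median 18S ribosomal RNA control signal (log2, as deposited) in the 15 arrays, with points for arrays and bars for the mean ± SD of each group of 3. Htt25Q array 1 stands at 2.48 in the first and the ume1 deletion array 1 at 10.4 in the second, and both groups of the second processing set lie at 9.53 or above.

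Htt103Q was compared with Htt25Q to ask what the expanded repeat changes. Among measured genes, 12 of 37 cytosolic chaperones and 8 of 27 genes of cell wall integrity rose, and 35 of 126 genes of ribosome biogenesis and 8 of 18 of the phosphate regulon fell. Of these lists, only the chaperones kept their call with an estimated correlation (adjusted p = 0.00335). The Hsp70 chaperone SSA4 (chromosome V, 364589 to 366517) went from 7.12 ± 0.164 to 10.1 ± 0.278 (SD, n = 3), 7.75-fold, with a log2 fold change of 2.95 ± 0.121 (SE, adjusted p = 2.34e-07). BTN2 (chromosome VII, 772454 to 773686), which sorts misfolded proteins, rose by 3.28 ± 0.327 (0.000351), and HSP30, a heat shock protein of the plasma membrane, by 3.58 ± 0.392 (0.000629). The cell wall protein PIR3 (chromosome XI, 144401 to 145378) rose by 4.72 ± 0.478 (0.000365), from 7.08 ± 1.32 to 11.8 ± 0.3. PHO5 (chromosome II, 429548 to 430951), a secreted acid phosphatase, changed by −2.67 ± 0.353 (0.00164), and PHO84 (chromosome XIII, 24037 to 25800), a phosphate transporter, by −2.19 ± 0.356 (0.00568).

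Of 9275 probe sets, 412 were called in this comparison, 191 higher and 221 lower. The other large rises were DAK2, a dihydroxyacetone kinase (4.48 ± 0.164, adjusted p = 1.06e-07), ROQ1, a regulator of the ubiquitin ligase Ubr1 (3.90), NCW2, of the cell wall (3.77), BAG7, a regulator of the GTPase Rho1 (3.57), CPP3 (3.35) and TMA10 (3.15). The other large falls were the drug transporter AQR1 (−3.23 ± 0.382, 0.000961), PHM6 of the phosphate regulon (−3.06 ± 0.237, 6.63e-05), YOR338W (−2.44) and PRM7 (−2.38, and −2.27 for its other probe set). The hexose transporter HXT2 (−2.33), the glycerophosphoinositol transporter GIT1 (−2.28), BIO5 of biotin synthesis (−2.26) and YGR079W (−2.20) followed. MBF1 itself rose by 1.08 (0.000925).

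Ribosome biogenesis was the group with the most falls by number, though not by share. Of its 126 measured genes 35 were lower, 0 higher and 91 not passing, and 88 were lower when adjusted over the list alone. The list median was −0.83 (camera adjusted p = 2.69e-31), and adjusted p = 0.175 with an estimated correlation. DBP2 (−1.84, other probe set −1.71), NSR1 (−1.68), SSF1 (−1.65) and SDA1 (−1.44) fell. The list median of Htt25Q array 1 lay 1.44 above the Htt103Q mean, against 0.549 and 0.524 in the other Htt25Q arrays. RNA polymerase I and III genes had 4 of 27 lower, 23 not passing and 8 lower adjusted over the list alone, with a median of −0.33 (0.000109; adjusted p = 0.175 with an estimated correlation), RRN11 (−1.57) and RPC37 (−0.94) among them. Cytosolic ribosomal proteins had a median of −0.12 with 0 of 80 called by limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, and camera adjusted p = 0.049 (0.567 as adjusted p with an estimated correlation). This call was lost without Htt25Q array 1 (adjusted p = 0.322), Htt25Q array 3 (0.0524) or Htt103Q array 3 (0.361).

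Cytosolic chaperones had 12 of 37 genes higher, 0 lower and 25 not passing, and 16 higher adjusted over the list alone, with a median of 0.37 (camera adjusted p = 3.43e-09), a call that held at adjusted p = 0.00335 with an estimated correlation. HSP26 rose by 2.44 and SSA3 by 1.65. The proteasome list had 4 of 47 higher and 43 not passing, 8 higher adjusted over the list alone, and a median of 0.25 (1.93e-05; adjusted p = 0.0041 with an estimated correlation). RPN4, the transcription factor of proteasome genes, rose by 1.48, PRE8 by 0.78, RPN7 by 0.72 and PRE10 by 0.47. General stress genes under Msn2 and Msn4 had 8 of 57 higher, 0 lower and 49 not passing, with 16 higher and 1 lower adjusted over the list alone (median 0.50, 2.22e-09; adjusted p = 0.353 with an estimated correlation), MOH1 (2.27) among them. Their list median in Htt25Q array 1 was −1.09 relative to the Htt103Q mean, against −0.22 and −0.15 in the other Htt25Q arrays, and without array 1 the mean change went from 0.67 to 0.37 (adjusted p = 0.000329). Cell wall integrity genes had 8 of 27 higher, 19 not passing and 11 higher adjusted over the list alone (median 0.60, 1.64e-07; adjusted p = 0.246 with an estimated correlation). PST1 rose by 1.94, the kinase SLT2 of this pathway by 1.57 and SPI1 by 1.34. Here too Htt25Q array 1 stood apart, at −1.09 against −0.23 and −0.15, and the mean change went from 0.75 to 0.48 without it (adjusted p = 0.000107).

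The phosphate regulon had 8 of 18 genes lower, 1 higher and 9 not passing, with 11 lower and 2 higher adjusted over the list alone (median −0.60, 6.51e-07; adjusted p = 0.175 with an estimated correlation). Its median in Htt25Q array 1 was 1.23, against 0.19 and 0.42 in the others, and its mean change went from −0.95 to −0.78 without that array (adjusted p = 8.44e-06). In fatty acid and phospholipid synthesis PSD1 (−0.69) was the only 1 of 27 genes lower, with 7 lower adjusted over the list alone, a median of −0.33 and adjusted p = 0.00265, which held at adjusted p = 0.0398 with an estimated correlation. The zinc regulon had 2 of 15 lower, IZH1 (−1.17) and IZH2 (−0.83), with 4 lower and 1 higher adjusted over the list alone (median −0.35, 0.0133; adjusted p = 0.353 with an estimated correlation), and was not called without Htt25Q array 1 (0.129) or Htt103Q array 2 (0.0784). Amino acid synthesis under Gcn4 had 3 of 63 lower, LYS20 (−1.50), ARO1 (−0.59) and HIS2 (−0.42), and 3 lower adjusted over the list alone (median −0.20, 0.00653; adjusted p = 0.492 with an estimated correlation). It was not called without Htt25Q array 3 (0.801).

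Mitochondrial ribosomal proteins had a median of 0.21 over 73 genes with 0 called by limma, 0 adjusted over the list alone and 20 at an unadjusted p under 0.05 (camera adjusted p = 1.35e-05; adjusted p = 0.246 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of 0.27 with 0 of 42 called by limma, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 (0.00653; adjusted p = 0.567 with an estimated correlation), and were not called without Htt25Q array 1 (mean 0.01, adjusted p = 0.630), which stood at −0.81 against 0.04 and −0.07 in the others, or Htt103Q array 2 (0.0541). The tricarboxylic acid and glyoxylate cycle had 5 of 28 higher and 5 adjusted over the list alone (median 0.27, 0.01; adjusted p = 0.0591 with an estimated correlation; 0.0678 without Htt25Q array 3), with IDP2 (1.26) and SFC1 (0.97). Tubulin and actin cytoskeleton genes had 3 of 30 higher and 3 adjusted over the list alone (median 0.18, 0.00653; adjusted p = 0.0501 with an estimated correlation), MYO3 (0.46), ARC19 (0.37) and CAP1 (0.35). In the iron regulon ISU2 (1.15) rose and BIO5 fell among 30 genes, with 2 higher and 1 lower adjusted over the list alone (median 0.36, 0.0391; adjusted p = 0.592 with an estimated correlation). The iron call was lost without Htt25Q array 2 (0.0971) or 3 (0.349) or Htt103Q array 1 (0.198) or 3 (0.287). Without Htt25Q array 1, at 0.39 against −0.49 and −0.71 in the others, the iron mean went from 0.44 to 0.77 (adjusted p = 0.000329).

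The remaining lists were not called in this comparison. Kynurenine and NAD biosynthesis had a median of −0.08 and 0 of 19 genes called by limma, 2 at an unadjusted p under 0.05 (0.789). Oxidative stress genes had 0.13 (0.0857), with SRX1, a sulfiredoxin, higher by 2.94 and FLR1 lower. Medians were −0.16 for translation factors and tRNA synthetases (0.054), −0.23 for ergosterol synthesis (0.0873), −0.18 for pyrimidine synthesis (0.0873), −0.12 for the unfolded protein response (0.298), −0.09 for anaerobic cell wall genes (0.298), 0.10 for glycolysis (0.353), −0.11 for purine synthesis (0.699) and −0.01 for hexose transport (0.896). They were near 0 for sulfur and methionine, peroxisome and cell cycle genes (each 0.789), and 0.12 for galactose utilisation (0.789). Early meiotic genes had 3 higher and 3 lower of 54 (0.939), SPO11 lower by −1.78 and SPO1 higher by 1.28 among them. Autophagy had a median of −0.04 and a mean of 0.12 (0.771), with ATG8 (1.40) and ATG1 (1.13) higher. The mating pathway had a median of −0.09 and a mean of 0.07 (0.789), with PRM5, PRM10 and PRM8 higher, and a-specific genes a median of −0.02 and a mean of 0.09 (0.789). The deleted and marker loci were not called (0.866). Histones (median 0.05) and alpha-specific genes (−0.11), with 4 measured each, were too few to test. Leaving out 1 array gave calls to translation factors (0.0233 without Htt25Q array 3, 0.0297 without Htt103Q array 2), pyrimidine synthesis (0.0386 without Htt25Q array 2) and oxidative stress genes (0.0444 without Htt103Q array 3).

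The 3 arrays of each group did not overlap for 1757 probe sets, 18.9% against the 10% of chance. The spread between the Htt25Q arrays was 1.37 times the pooled one. In deposited values 134 probe sets were called with the 9 arrays of the first set alone, 125 of them among the 412, and 438 with all 15 arrays. With only the 6 arrays compared 32 were called, 26 of them shared. Of the named genes, the first set alone kept 10 rises and 8 falls, and the groups compared alone 5 rises and 1 fall. The count was 191 without Htt103Q array 2, 217 without Htt103Q array 3 and 627 without both arrays in doubt.

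**Figure D3:**
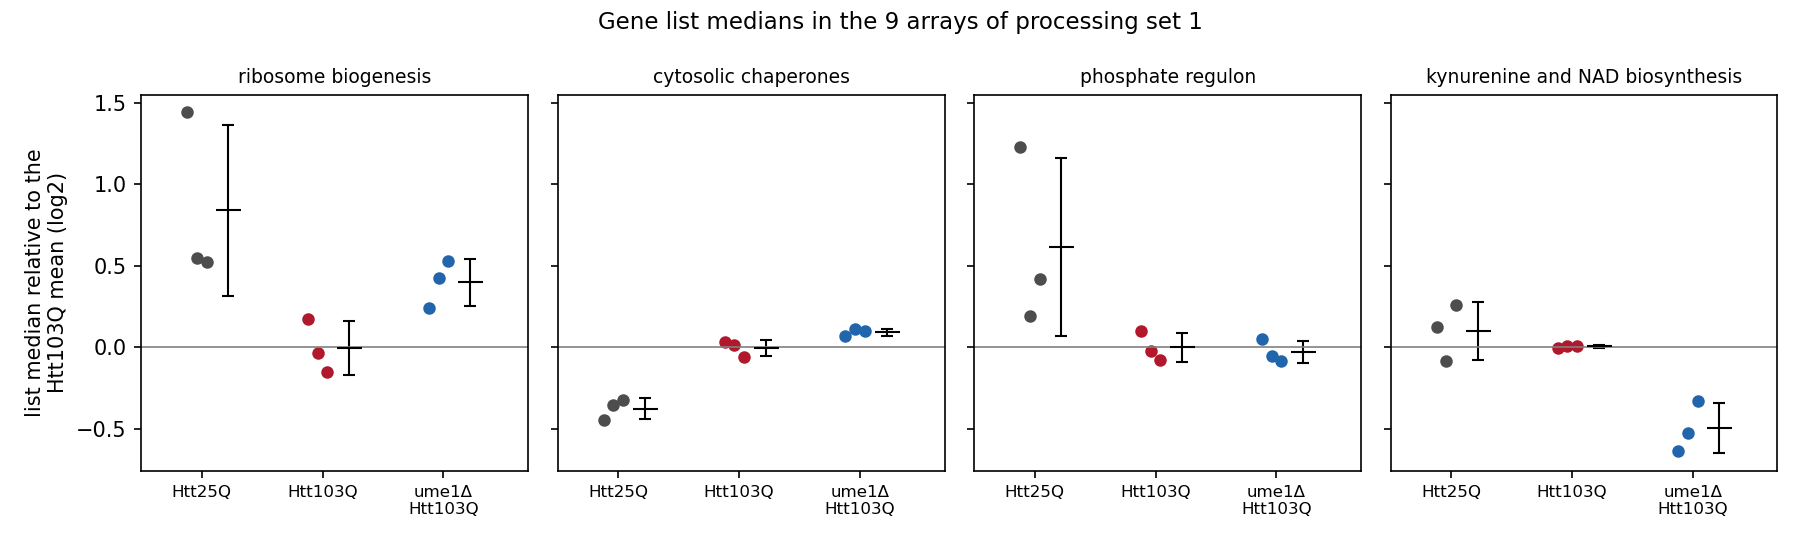
Median of 4 gene lists in each of the 9 arrays of the first processing set, as log2 relative to the Htt103Q mean, with points for arrays and bars for the mean ± SD of 3 arrays. In ribosome biogenesis the Htt25Q arrays stand at 0.524 to 1.44, and in kynurenine and NAD biosynthesis the ume1 deletion arrays stand between −0.634 and −0.330.

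The ume1 deletion was compared with Htt103Q in the same processing set. Of 19 genes of kynurenine and NAD biosynthesis, 5 were lower. BNA2 (chromosome X, 578860 to 580221), whose enzyme opens the kynurenine pathway, changed by −1.77 ± 0.295 (SE, adjusted p = 0.0094), BNA5 (chromosome XII, 605758 to 607119), the kynureninase, by −1.64 ± 0.36 (0.0389), and BNA4 by −1.55 ± 0.121 (5.74e-05). NRT1 (chromosome XV, 459480 to 461276), a nicotinamide riboside transporter, changed by −1.83 ± 0.156 (0.000112). In the other direction the oligopeptide transporter OPT1 (chromosome X, 33850 to 36249) rose by 1.91 ± 0.136 (2.87e-05).

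The count in this comparison was 241 probe sets, 148 higher and 93 lower. AQR1 (2.56 ± 0.382, 0.00526) and YOR338W (2.29), both lower in Htt103Q than in Htt25Q, were the largest rises. They were followed by ANB1, the hypoxic form of a translation factor (1.91 ± 0.285, 0.00526), EFM6, a methyltransferase (1.88), YKL183C-A (at least 1.88, since Htt103Q lay at the floor), ICY1 (1.77), YOL131W (1.65), the urea transporter DUR3 (1.61) and YKL068W-A (1.59). Falls were COS7 (−1.99, other probe set −1.38), the RNA-binding protein MIP6 (−1.92), SSP1, which acts in meiosis (chromosome VIII, 472744 to 474459; −1.88 ± 0.129, 2.09e-05), DAK2 (−1.84), IRC18 (−1.81), YIL014C-A (−1.69) and the decarboxylase FDC1 (−1.59). The calls of ICY1 and BNA5 were lost when any 1 of the 6 arrays was left out, and that of COS7 with 5 of them. YKL183C-A was lost with 3 of them, and YOL131W and DUR3 without Htt103Q array 2 or 3.

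Kynurenine and NAD biosynthesis had 5 of 19 genes lower, 0 higher and 14 not passing, with 9 lower adjusted over the list alone. The median was −0.57 (camera adjusted p = 1e-06), a call that held at adjusted p = 0.0367 with an estimated correlation. The mating pathway had 3 of 36 lower, FUS1 of cell fusion (−1.38), the pheromone receptor STE3 (−1.06) and the transcription factor STE12 (−0.72), with 12 lower and 1 higher adjusted over the list alone (median −0.25, 5.24e-06; adjusted p = 0.0506 with an estimated correlation). Genes specific to a cells had 0 of 7 called by limma, 4 lower at an unadjusted p under 0.05 and 4 lower adjusted over the list alone (median −0.69, 0.000985; adjusted p = 0.282 with an estimated correlation). Of the 4 genes specific to alpha cells, too few to test, 1 was lower, with a median of −0.48 and array medians of −0.51 to −0.44. The early meiotic list, part of which the Rpd3 complex with Ume6 represses, also holds sporulation genes such as SPS100 of the spore wall. It had 4 higher, 2 lower and 48 not passing, with 5 higher and 7 lower adjusted over the list alone (median 0.00, adjusted p = 0.962). A mixed list cannot show whether the genes that Ume6 represses changed. SSP1 (−1.88) and SPS100 (−1.18) fell, and REC104 (at least 1.36) and ACS1 (0.99) rose.

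Ribosome biogenesis genes had 9 of 126 higher, 0 lower and 117 not passing, with 14 higher adjusted over the list alone (median 0.38, 5.82e-13; adjusted p = 0.381 with an estimated correlation). DBP2 (1.21, other probe set 1.06), REX4 (0.84), RRS1 (0.80) and NSR1 (0.74) rose. RNA polymerase I and III genes had RRN3 (0.57) as the 1 rise, also 1 adjusted over the list alone (median 0.18, 0.00701; adjusted p = 0.315 with an estimated correlation). The zinc regulon had 3 of 15 higher, the membrane proteins IZH4 (1.5) and IZH1 (1.31) and the transporter FET4 (1.26), with 4 adjusted over the list alone (median 0.24, 0.000674; adjusted p = 0.177 with an estimated correlation). The tricarboxylic acid cycle had 3 of 28 higher, SFC1 (1.25), ACS1 and IDP2 (0.59), and 5 adjusted over the list alone (median 0.19, 0.00551; adjusted p = 0.0506 with an estimated correlation). Peroxisome genes had 3 of 33 higher, the carnitine proteins CAT2 (1.21) and CRC1 (1.13) and PEX4 (0.58), with 6 higher and 1 lower adjusted over the list alone (median 0.19, 0.0245; adjusted p = 0.0771 with an estimated correlation).

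Weaker list calls followed. Mitochondrial ribosomal proteins had a median of −0.09 with 0 called by limma, 0 adjusted over the list alone and 8 at an unadjusted p under 0.05 (0.0245; adjusted p = 0.533 with an estimated correlation), and were not called without Htt103Q array 2 (0.255) or the ume1 deletion array 2 (0.0778). Anaerobic genes had ANB1 and AAC3 (1.14) higher and 4 adjusted over the list alone (median 0.18, 0.0391; adjusted p = 0.284 with an estimated correlation), a call lost without the ume1 deletion array 1 (0.153), the array with high ribosomal RNA. Autophagy had ATG5 (0.79) higher and 4 adjusted over the list alone (median 0.08, 0.0407; adjusted p = 0.115 with an estimated correlation), lost without Htt103Q array 1 (0.151) or the ume1 deletion array 3 (0.0887). Cell cycle genes had CLB6 (−0.93), RNR1 (−0.79) and CLB5 (−0.29) lower and the inhibitor SIC1 (0.71) higher, with 3 lower and 1 higher adjusted over the list alone (median −0.09, 0.0435; adjusted p = 0.315 with an estimated correlation). That call was lost without Htt103Q array 1 (0.151) or 3 (0.0561) or the ume1 deletion array 3 (0.123). The list of deleted and marker loci was called through UME1 and BNA4 (mean −0.83, median 0, 0.00701; adjusted p = 0.0749 with an estimated correlation). The iron regulon was called only without Htt103Q array 2 (0.000345) or the ume1 deletion array 2 (0.00291), fatty acid synthesis only without Htt103Q array 3 (0.0398), and glycolysis and pyrimidine synthesis only without Htt103Q array 1 (both 0.047).

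Arrays of the groups did not overlap for 1894 probe sets, 20.4% against the 10% of chance. With the first set alone 46 probe sets were called, and 234 with all 15 arrays, both in deposited values. The former kept 6 of the 20 named genes (2 rises and 4 falls) and BNA4 (0.00901). With only the 6 arrays compared the count was 121, without Htt103Q array 2 it was 115, without Htt103Q array 3 it was 124, and without both arrays in doubt 460.

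Against Htt25Q, the ume1 deletion had 729 probe sets called, 388 higher and 341 lower. ROQ1 (4.86), PIR3 (4.64), BAG7 (4.47), HSP30 (4.3) and NCW2 (3.94) rose most, and PHM6 (−3.42), PHO5 (−2.75), GIT1 (−2.55), PHO84 (−2.38) and SPO11 (−2.34) fell most. Chaperones had 16 of 37 higher, 1 lower and 20 not passing, with 21 higher and 1 lower adjusted over the list alone (median 0.55, 4e-09; adjusted p = 0.00278 with an estimated correlation). Kynurenine and NAD genes had 8 of 19 lower and 11 not passing, with 12 lower and 2 higher adjusted over the list alone (median −0.75, 0.000141; adjusted p = 0.0409 with an estimated correlation). The proteasome had 7 of 47 higher, 10 adjusted over the list alone (0.23, 4.66e-05; adjusted p = 0.00532 with an estimated correlation), and fatty acid synthesis 8 of 27 lower, with 12 lower and 1 higher adjusted over the list alone (−0.58, 0.000263; adjusted p = 0.0104 with an estimated correlation). Ribosome biogenesis had 9 of 126 lower, also 9 adjusted over the list alone (−0.40, and −0.18 without Htt25Q array 1; 1.04e-07; adjusted p = 0.477 with an estimated correlation), and the phosphate regulon 9 of 18 lower and 2 higher, with 12 and 2 adjusted over the list alone (−0.89, 1.02e-05; adjusted p = 0.177 with an estimated correlation). Relative to the Htt103Q mean, the phosphate list median was 1.23 in Htt25Q array 1 and 0.19 and 0.42 in the other Htt25Q arrays, so array 1 enlarged that fall. The 3 arrays of each group did not overlap for 21.4% of probe sets against the 10% of chance. The count in deposited values was 252 with the first set alone and 787 with all arrays. In quantile normalized values it was 75 with only the groups compared, 463 without the ume1 deletion array 2 and 1746 without both arrays in doubt.

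The mbf1 and bna4 deletions share a processing set, and their comparison was chosen after the sets were seen. The bna4 deletion held much more RNA of cell wall genes that yeast makes when oxygen is low. The mannoprotein DAN1 (chromosome X, 708811 to 709707) had 9.35 ± 0.227 (SD, n = 3) in the bna4 deletion and 2.11 ± 0.0219 in the mbf1 deletion, close to the floor, a log2 fold change of at least −7.25 (adjusted p = 7.29e-13). TIR1 (chromosome V, 175248 to 176012) had 11.7 ± 0.0663 and 4.83 ± 0.0635 (−6.88 ± 0.19, SE, 1.77e-09). The mbf1 deletion was higher in LYS9 of lysine synthesis (chromosome XIV, 714048 to 715388; 4.44 ± 0.0897, 8.78e-11) and INO1 of inositol synthesis (chromosome X, 134332 to 135933; 3.48 ± 0.198, 1.54e-06).

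In all, 978 probe sets were called, 532 higher and 446 lower in the mbf1 deletion. Other rises were the citrate carrier CTP1 (3.43), the acid transporter PDR12 (2.83) and the glycerol transporter STL1 (2.61). NCR1 (3.52), FAS2 (3.06), SPT5 (3.05), NUP170 (2.73) and ECM29 (2.63) were named through 1 probe set each, and others of the same genes lay lower, down to −1.41 for NUP170. The call of NCR1 (0.0327) was lost when any 1 of the 6 arrays was left out, and those of FAS2 and NUP170 with 5 of them. With the replicate block NCR1 (0.0503) and FAS2 (0.0624) were not called. Falls were SPG1 (−5.16) and SPG4 (−4.69), needed in stationary phase, HES1 of sterol transport (−3.91), FHN1 (−3.89), the acetate transporter ADY2 (−3.75), HXT2 (−3.69), SPS100 of the spore wall (−3.48), and 1 probe set of the glucan synthase GSC2 (−3.97), whose others ranged from −3.9 to 2.56.

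The anaerobic list had 8 of 11 genes lower, 0 higher and 3 not passing, and 9 lower adjusted over the list alone (median −1.59, 4.36e-12; adjusted p = 0.00642 with an estimated correlation), TIR3 (−3.38) and ANB1 (−3.22) among them. Cell cycle genes had 8 of 41 higher and 33 not passing, 12 adjusted over the list alone (0.36, 3.42e-06; adjusted p = 0.0482 with an estimated correlation), with DSE4 (1.16), PRY3 (1.06) and the cyclin CLB6 (0.75). The tricarboxylic acid and glyoxylate cycle had 8 of 28 lower and 1 higher, with 10 and 3 adjusted over the list alone (−0.22, 0.0112; adjusted p = 0.0482 with an estimated correlation), with PCK1 (−1.83), CIT2 (−1.70) and SFC1 (−1.44). Cytoskeleton genes had 6 of 30 higher, 7 adjusted over the list alone (0.16, 0.0112; adjusted p = 0.0482 with an estimated correlation), with the myosin MYO5 (1.26). The mating pathway had 9 of 36 higher, 11 adjusted over the list alone (0.27, 0.0112; adjusted p = 0.186 with an estimated correlation), the agglutinins AGA1 (1.56) and AGA2 (1.24) among them, and a-specific genes 2 of 7, with 3 adjusted over the list alone (0.65, 0.0149; adjusted p = 0.503 with an estimated correlation).

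Fatty acid and phospholipid synthesis had 7 of 27 higher and 2 lower, with 7 and 3 adjusted over the list alone (median 0.24, 0.0149; adjusted p = 0.0574 with an estimated correlation), with PSD1 (1.48) and CHO2 (1.12). It was not called in the second set alone (0.0783). Cell wall integrity had 5 of 27 higher, 7 adjusted over the list alone (0.33, 0.00537; adjusted p = 0.624 with an estimated correlation), with MNN1 (1.00) and the chitin synthase CHS3 (0.88). Hexose transport had 4 of 13 lower and 1 higher, also 4 and 1 adjusted over the list alone (median −0.07, 0.0161; adjusted p = 0.153 with an estimated correlation), the transporters HXT5 (−3.07) and HXT3 (−1.85) with HXT2 against STL1. The iron regulon had 3 of 30 lower, 2 adjusted over the list alone (−0.33, 0.0384; adjusted p = 0.705 with an estimated correlation), FIT3 (−2.96), AFT2 (−0.93) and MRS4 (−0.65), and was not called without the mbf1 deletion array 1 (0.0508) or 3 (0.0869). Gcn4 targets had 10 higher, 4 lower and 49 not passing, with a median of 0.00, a mean of 0.24 and adjusted p = 0.443; ARG8 (2.56) of arginine synthesis rose and SNZ1 (−2.80) and SER3 (−2.38) fell. The arrays did not overlap for 3457 probe sets, 37.3% against the 10% of chance. The count was 630 without the bna4 deletion array 2, and calls came to ribosome biogenesis without the mbf1 deletion array 1 (0.0114), the proteasome without the bna4 deletion array 1 (0.0386) or the mbf1 deletion array 3 (0.0224), and oxidative phosphorylation without the bna4 deletion array 1 (0.0423).

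**Figure D4:**
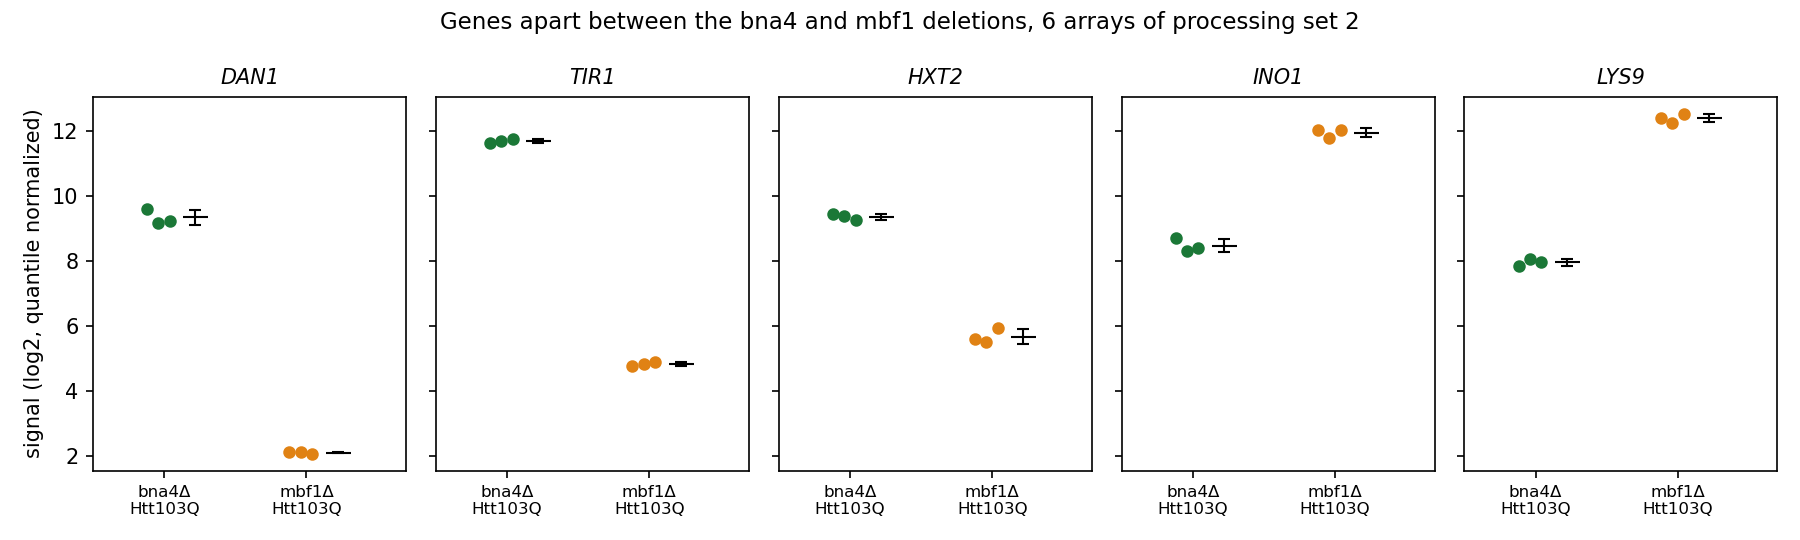
Log2 signal of DAN1, TIR1, HXT2, INO1 and LYS9 (vertical axis) in the 6 arrays of the bna4 and mbf1 deletions, with points for arrays and bars for the mean ± SD of 3 arrays. DAN1 stands at 9.35 in the bna4 deletion and 2.11 in the mbf1 deletion, and LYS9 at 7.97 and 12.4.

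The bna4 deletion was compared with Htt103Q across the processing sets, so strain and set cannot be parted. TIR1 (7.61 ± 0.19, adjusted p = 2.01e-10), DAN1 (at least 7.31, Htt103Q at the floor) and CHA1, a serine and threonine deaminase (6.89, chromosome III, 15798 to 16880), were the largest rises, followed by the ribosomal RNA RDN18-1 (5.48), YDR524W-C (5.43), YDR034C-A (5.30), YDL009C (4.93), COB (4.82), RDN37-1 and RDN25-1 (both 4.71), with the 18S controls also brighter in the second set. The fatty acid synthase genes FAS1 (−7.25) and FAS2 (−5.66) and the glucan synthase FKS1 (−5.89) were named as falls through 1 probe set each. Other probe sets of FAS1 ranged from −6.07 to 0.157. DAK2 fell to the floor (at least −5.43), and 6 of the 10 largest falls were tRNA genes. Sulfur genes had 15 of 32 higher and 1 lower, also 15 and 1 adjusted over the list alone (median 1.06, 9.65e-06; adjusted p = 0.14 with an estimated correlation), and anaerobic genes 8 of 11 higher, 8 adjusted over the list alone (1.49, 7.55e-06; adjusted p = 0.1 with an estimated correlation). Gcn4 targets had 28 of 63 higher and 5 lower, with 30 and 6 adjusted over the list alone (0.45, 6.47e-05; adjusted p = 0.504 with an estimated correlation), ribosome biogenesis 61 of 126 higher and 5 lower, with 64 and 5 (0.62, 3.04e-09; adjusted p = 0.699 with an estimated correlation), and purine synthesis 11 of 24 higher and 2 lower, with 11 and 2 (0.56, 0.00624; adjusted p = 0.504 with an estimated correlation). In total 4088 probe sets were called, 1932 higher and 2156 lower, against 2730 higher and 1382 lower in deposited values and 1698 and 3848 with centred arrays, and 68.8% did not overlap, against the 10% of chance. General stress genes were called only without Htt103Q array 1 (0.0394) or the bna4 deletion array 1 (0.0479), and ergosterol synthesis only without Htt103Q array 1 (0.0447).

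The mbf1 deletion against Htt103Q had the same limit. CHA1 (6.70, adjusted p = 5.82e-10), the arginine gene ARG3 (6.34, 0.00103), YDR034C-A (5.57), PUF3 (4.80), YDR524W-C (4.70), RDN18-1 (4.66), YDL009C (4.50), LYS20 of lysine synthesis (4.24), YFL067W (at least 4.10) and YLR358C (at least 3.86, both with Htt103Q at the floor) rose most, and FAS1 (−5.46), DAK2 (at least −5.43) and FKS1 (−4.56) were among the falls, with tRNA genes as the rest. Other probe sets of FAS1 reached 1.15. Gcn4 targets had 26 of 63 higher and 5 lower, with 27 and 5 adjusted over the list alone (median 0.43, 9.73e-07; adjusted p = 0.621 with an estimated correlation). Sulfur genes had 14 of 32 higher, also 14 adjusted over the list alone (0.71, 1.24e-05; adjusted p = 0.259 with an estimated correlation), and ribosome biogenesis 48 of 126 higher and 3 lower, with 50 and 3 (0.53, 7.37e-10; adjusted p = 0.802 with an estimated correlation). General stress genes had 21 of 57 lower and 2 higher, with 22 and 2 (−0.43, 0.0261; adjusted p = 0.895 with an estimated correlation), the phosphate regulon 9 of 18 lower, with 9 lower and 1 higher (−0.70, 0.0261; adjusted p = 0.823 with an estimated correlation), and autophagy 11 of 28 lower and 2 higher, with 15 and 2 (−0.39, 0.0396; adjusted p = 0.259 with an estimated correlation). Purine synthesis had 6 of 24 higher and 2 lower, also 6 and 2 (0.31, 0.0261; adjusted p = 0.624 with an estimated correlation), and translation factors 8 of 47 higher and 1 lower, with 6 and 1 (0.15, 0.0396; adjusted p = 0.731 with an estimated correlation), with a mean of −0.18 when arrays were centred. Calls were lost without the mbf1 deletion array 1 for general stress genes (0.0847) and for purine synthesis, autophagy and translation factors (each 0.0783), without Htt103Q array 2 for autophagy (0.0525) and without Htt103Q array 3 for autophagy (0.0582) and translation factors (0.0639), while the iron regulon was called without Htt103Q array 2 (0.00485). In total 3389 probe sets were called, 1614 higher and 1775 lower, against 2634 and 990 in deposited values and 1472 and 3549 with centred arrays, and 57.8% did not overlap, against the 10% of chance.

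Against Htt25Q, across the sets as well, 4133 probe sets were called in the bna4 deletion, 1918 higher and 2215 lower (2700 and 1445 in deposited values, 1643 and 4102 with centred arrays), and 3543 in the mbf1 deletion, 1664 higher and 1879 lower (2659 and 1054 in deposited values, 1473 and 3897 with centred arrays). DAN1 (at least 7.31), TIR1 (7.30), CHA1 (7.15), RDN18-1 (5.69) and RDN37-1 (5.48) rose most in the bna4 deletion, and FAS1 (−5.28), PHM6 (−4.88), the tRNA YNCB0011C (at least −4.35), FKS1 and the zinc transporter ZRT1 (both −4.25) fell most. In the mbf1 deletion CHA1 (6.95), YDR034C-A (5.63), PUF3, RDN18-1 (both 4.88) and ARG3 (4.75) rose most, and PHO84 (−5.66), PHM6 (−4.95), SPL2 (at least −4.53), YNCB0011C (−4.30) and YNCM0035C (at least −4.13) fell most.

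Changes in all 3 deletion strains against Htt103Q covered 85 probe sets, 51 higher and 34 lower, and 95 in deposited values, 78 higher and 17 lower. The bna4 and mbf1 deletions share a processing set and most of their calls, and 35.9 would be expected in all 3 if the calls of the ume1 deletion fell at random among those, a number that leaves out the effect of the shared Htt103Q arrays. AQR1 rose by 4.10, 2.78 and 2.56 in the bna4, mbf1 and ume1 deletions, the amino acid transporter DIP5 by 4.54, 3.05 and 1.46, and ANB1 by 4.31, 1.1 and 1.91. DAK2 changed by at least −5.43 in the bna4 and mbf1 deletions, at the floor, and by −1.84 in the ume1 deletion, the mitochondrial gene COX3, in the same order, by −2.84, −2.86 and −1.40, and the allantoin transporter DAL4 by −1.91, −1.93 and −1.54. YOR338W, ICY1, YKL183C-A and YKL068W-A rose in all 3. For these 10 genes in the ume1 deletion, 1 call was kept with the first set alone, 6 with only the groups compared, 9 with the replicate block and 6 in every fit with 1 array left out. AQR1 and YOR338W were also lower, and DAK2 higher, in Htt103Q than in Htt25Q. At these genes the shared Htt103Q arrays thus stood apart from all other groups, and whether that gave the shared changes was not tested. The count was 38 without Htt103Q array 2, 40 without Htt103Q array 3 and 54 without the bna4 deletion array 2. The F test called 4314 probe sets among the strains, 46.5%, a test that spans the processing sets. Genes set apart in the bna4 deletion were DAN1, TIR1, HES1 (3.78), ADY2 (3.37) and SPS100 (3.56), and in the mbf1 deletion ARG3, LYS9 (3.65), the small nuclear RNA SNR14 (−3.48), PHO84 (−3.47) and CTP1 (3.13). Those apart in the ume1 deletion, CHA1, YDR034C-A, FAS1, PUF3 and FKS1, part strains of different sets.

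The deletions were also compared with the effect of the long repeat. The covariance of the change in the ume1 deletion with the change of Htt103Q against Htt25Q was −0.0468, against −0.0200 from the shared Htt103Q arrays alone, a difference of −0.0268. With the Htt103Q arrays split it was −0.0270, with a range of −0.0483 to 0.00027 over the splits. Of the 412 probe sets called between Htt103Q and Htt25Q, 39 (9.47%) were called the opposite way in the ume1 deletion, against 1.62% in simulations where the deletion changes nothing, and 9 the same way. AQR1, YOR338W, DBP2 and NSR1 were among the 39, and 236 of the 412 were still called the same way against Htt25Q. The simulations took the measured changes as true and drew noise for each probe set separately, so 1.62% may be too low. Across the sets, the covariance was −0.126 for the bna4 and −0.111 for the mbf1 deletion, against −0.0198 and −0.0199, with 207 (50.2%) and 205 (49.8%) of the 412 called the opposite way and 58 and 33 the same way, where 44.1% and 36.5% of all probe sets were called. The references for the covariance hold no difference between the processing sets. Neither the simulations nor the split removes a deviation common to all Htt103Q arrays, which would also give a negative covariance.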

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

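Of the tests in this part, the one of shared changes against Htt25Q was chosen before its result was seen, and all others, as well as the comparison of the mbf1 with the bna4 deletion, were chosen after.

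Results that differ between the mbf1 and bna4 deletions stood out by a direct test of the difference, which called 978 probe sets. The mean log2 difference of the list, mbf1 minus bna4, was −2.39 for anaerobic cell wall genes, −0.61 for hexose transport, −0.49 for the tricarboxylic acid and glyoxylate cycle and −0.49 for the iron regulon. It was 0.68 for a-specific genes, 0.39 for cell cycle genes, 0.38 for fatty acid and phospholipid synthesis, 0.36 for cell wall integrity, 0.32 for the mating pathway and 0.22 for the cytoskeleton. With an estimated correlation the calls of the anaerobic, tricarboxylic acid, cell cycle and cytoskeleton lists were kept, at adjusted p = 0.00642 for the first and 0.0482 for the others, and those of the other lists were lost, with adjusted p from 0.0574 to 0.705.

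Signal appeared in control probe sets that the comparisons do not use. The spike controls DapX, LysX, PheX and TrpnX were each bright in 1 or more arrays of the first set and dark in the second. DapX stood at 13.2 and 13.6 in Htt25Q arrays 1 and 2, 13.5 in Htt103Q array 1 and 13.6 in the ume1 deletion array 3. LysX stood at 11.4 in Htt25Q array 3 and 12.3 in the ume1 deletion array 1. PheX stood at 12.6 in Htt103Q array 2 and the ume1 deletion array 2, and TrpnX at 12.0 in Htt103Q array 3. The antisense control CreX-3_st had a mean of 4.59 in the second set and 2.13 in the first. The 18S ribosomal RNA controls had a median of 11.2 in the bna4 deletion array 3.

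Against Htt103Q 4088 probe sets differed in the bna4 and 3389 in the mbf1 deletion, and 68.5% of the bna4 calls went the same way in mbf1, which a set effect and a shared strain effect could both give, so these cannot be told apart. Against Htt103Q arrays that stand apart as the cause, 75.5% of the shared changes (2113 of 2799) were also called against Htt25Q in both strains. The 978 probe sets between both strains lie within 1 set, so a difference between the sets does not account for them. A difference in handling between the arrays of these strains within the set was not tested. Their 18S controls lay at 11.1 to 11.2 in the bna4 and 9.53 to 10.7 in the mbf1 deletion. Probe sets of 1 gene spread 1.99 times as widely in the comparisons across the sets as in the widest within a set (medians 1.61 and 0.807 over 168 genes), as a difference in labelling or fragment length would give, a test prompted by the disagreeing probe sets of FAS1 and FKS1. A response shared by both deletion strains stays open as well.

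Ribosome biogenesis genes were lower in Htt103Q than in Htt25Q, and Htt25Q array 1 had the raised 3' signal of degraded RNA. Without that array the list median was −0.53, with 38 genes lower (camera adjusted p = 2.0e-25, and adjusted p = 0.159 with an estimated correlation), and the other two Htt25Q arrays stood at 0.55 and 0.52 relative to Htt103Q, which argues against degradation as the whole cause. Htt103Q arrays that stand apart could also give the pattern; the ume1 deletion against Htt25Q, which uses none of them, had −0.40, but −0.18 without Htt25Q array 1, so this stays open. That the verdict must hold without this array too was required after the −0.40 had been seen. A response to the long repeat remains a hypothesis.

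Kynurenine and NAD genes were lower in the ume1 deletion than in Htt103Q, and the ume1 deletion array 1 had high ribosomal RNA. Without that array the median was −0.39 with 5 genes lower (camera adjusted p = 7.2e-07, and adjusted p = 0.0454 with an estimated correlation). The other arrays of the strain stood at −0.53 and −0.33 relative to Htt103Q. The Htt103Q arrays lay within 0.01 of 0, in part because the values are relative to their own mean. The fall without array 1, and in each of the other arrays of the strain, argues against that array as the whole cause. A part of it in the size stays open, since −0.39 falls short of the bound of −0.4 set for that, and the test on the other two arrays was added after their values were seen. Htt103Q arrays that stand apart do not account for it, since the ume1 deletion against Htt25Q had −0.75, and −0.59 without Htt25Q array 1 (camera adjusted p = 6.94e-05, and adjusted p = 0.0603 with an estimated correlation). Loss of UME1 lowering this pathway, BNA4 included, may be the cause, as a hypothesis.

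Other splits of the same arrays were counted. For 3 against 3 arrays there are 10 splits, so the share with as many calls, here 1 of 10 for the real one, is never under 0.1. Real counts and the highest of the other splits were 412 and 3 for Htt103Q against Htt25Q, 241 and 25 for the ume1 deletion against Htt103Q, 729 and 0 for it against Htt25Q, 978 and 0 for mbf1 against bna4, 4088 and 0 for bna4 and 3389 and 2 for mbf1 against Htt103Q, and 4133 and 0 and 3543 and 48 for them against Htt25Q. For the F test among the strains 1 of 100 splits, the real one, reached 4314, a share under 0.05. The highest other, 3110, points to a structure of the samples. The 3 other splits that kept the ume1 deletion arrays in 1 group gave 2998 to 3110. Those that did not gave at most 739, so the structure is the ume1 deletion against the second set, where strain and set cannot be parted. The splits with at most 739 mix the processing sets within a group and the real one does not. The share therefore does not exclude chance apart from the sets. For the changes in all 3 strains 1 of 100 splits reached 85, with 28 as the highest other. Most splits of these arrays also mix the sets, so chance apart from the sets is not excluded here either.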

How the results depend on the processing

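The fits to 1 processing set alone and without both arrays in doubt were chosen after seeing the data. The other alternatives were chosen in advance, apart from the cut-off of the dim filter. Where a value moved and no cause is given, the cause was not tested. Without Htt25Q array 1 and the ume1 deletion array 1, counts were 627 for Htt103Q against Htt25Q, 460 for the ume1 deletion against Htt103Q, 1746 for it against Htt25Q and 184 for all 3 strains, and the bna4 covariance was −0.0992. With the processing set alone, in deposited values, they were 134, 46 and 252 for these comparisons of the first set, against 438, 234 and 787 with all 15 arrays in deposited values, so leaving out the second set lowered them. With only the groups compared they were 32, 121 and 75 for the same comparisons, with 2252 for mbf1 against Htt25Q and 193 for all 3 strains. Array weights gave 810, 1512 and 2299, with 2982 for mbf1 against bna4, 6951 for the F test and 537 for all 3 strains. With 1 probe set per gene, and so fewer tested, mbf1 had 2198 against Htt103Q and 2284 against Htt25Q, and with centred arrays 5370 against Htt25Q. A fold change of at least 1.5, a stricter criterion, left 49 for all 3 strains.

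The covariance with the effect of Htt103Q was −0.156, −0.138 and −0.0572 for bna4, mbf1 and ume1 with dim probe sets left out, and −0.106, −0.0913 and −0.0270 with the Htt103Q arrays split. The split removes noise that each Htt103Q array has on its own, but not a deviation common to all 3. For mbf1 the covariance was −0.126 with deposited values and with centred arrays. With 1 array left out it ranged from −0.151 to −0.0990 for bna4, −0.132 to −0.0890 for mbf1 and −0.0686 to −0.0348 for ume1. Counts with 1 array left out ranged from 191 to 558 for Htt103Q against Htt25Q, 115 to 239 for ume1 against Htt103Q, 463 to 868 for ume1 against Htt25Q, 630 to 917 for mbf1 against bna4 and 38 to 98 for all 3 strains. The lowest came without Htt103Q array 2 in the first, second and last, without the ume1 deletion array 2 in the third and without the bna4 deletion array 2 in the fourth.

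Directions reversed only across the processing sets, under deposited values or centring. For mbf1 against Htt103Q TIR3 was 0.14 with deposited values, and with centring GAL1 was −0.64, DAN1 −0.34, ATP3 −0.081 and HTB1 −0.077. For lists the direction was that of camera, against all other genes, so a reversal need not change the sign of the mean. Mean changes of cytosolic ribosomal proteins were −0.22 deposited and −0.61 centred for bna4 and −0.15 and −0.56 for mbf1, oxidative phosphorylation −0.17 and −0.58 for mbf1, and translation factors −0.18 centred for mbf1. With an estimated correlation 44 list calls were lost and none gained over the comparisons other than those of deletion strains with Htt25Q. Over the same comparisons fry, which does not set the members against other genes, lost 9 calls and gained 39, most of the gains across the sets, with 24 lists against 5 for bna4 and 19 against 8 for mbf1 versus Htt103Q. For the strains against Htt25Q, with an estimated correlation, 0 of 8, 1 of 5 and 5 of 13 calls held for bna4, mbf1 and ume1. Among the named genes' results, 142 calls were lost with only the groups compared and 100 with the set alone, with 586 lost and 25 gained over all fits with 1 array left out.

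With replicate number as a replicate block, counts were 425, 4129, 3474 and 230 for Htt103Q against Htt25Q and for bna4, mbf1 and ume1 against Htt103Q, and 970 for mbf1 against bna4. Of 769 named results 27 were lost and 10 gained.

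Alternatives for linear values and for probe sets of another yeast species were not run, since the values are log2 and the array holds none. Signal over background limits genes near the floor, where 7.80% to 13.8% of probe sets per array lay at the lowest value.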

Other observations

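The values in this part are from comparisons and lists already described, read after the results were seen, and no new test was added.

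In lists that were not called between the mbf1 and bna4 deletions, single genes differed. Of the zinc regulon 4 of 15 genes were lower in the mbf1 deletion (list adjusted p = 0.0846), and of the phosphate regulon 5 of 18 were lower and 1 higher (0.187). The membrane proteins IZH4 (−2.50, adjusted p = 1.18e-06), IZH1 (−0.96) and IZH2 (−0.91) were lower, as were the phosphate transporters PHO84 (−3.41, 0.00015) and PHO89 (−2.98, 0.000125) and the regulator SPL2 (at least −1.03). The peroxisomal catalase CTA1 was lower by −2.81 (9.28e-06) while the beta-oxidation regulator PIP2 (1.29) and PEX11 (1.01) were higher. Among chaperones, SSA4 was higher by 1.53 (1.88e-05) and APJ1 lower by −1.82 (0.000155).

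Of ergosterol synthesis 5 of 28 genes were lower and 3 higher (list adjusted p = 0.327). The regulator UPC2, which acts when sterol or oxygen is low, was lower by −1.76 (0.000624) in the mbf1 deletion, as was HES1, while ERG5 (1.11) and HMG1 (1.1) were higher. CAR1 (−2.07) and CAR2 (−1.71) of arginine breakdown were lower and ARG8 of arginine synthesis was higher, genes put side by side after their values were seen. In kynurenine and NAD biosynthesis, BNA1 (0.80, 0.0186) and NRT1 (1.11, 0.00105) were higher in the mbf1 deletion, as was BNA4, deleted in the other strain, and PHO8 (−0.99, 0.00584) was lower, 4 of 19 genes called.

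Of 92 probe sets of tRNA genes, 81 were lower in the bna4 deletion against Htt103Q, with a median of −2.66, and 72 in the mbf1 deletion, with −2.65, both across the processing sets. By limma 0 of them were called between Htt103Q and Htt25Q, between the ume1 deletion and Htt103Q and between the mbf1 and bna4 deletions, with 2, 12 and 0 at an unadjusted p under 0.05 and a median of −0.39 in the second of these. Against Htt25Q, in the same set, 5 were lower in the ume1 deletion. Chromosome medians lay between −0.23, chromosome III in the bna4 deletion, and 0.09, chromosome XI in Htt103Q against Htt25Q, well short of the change of 1 on the log2 scale that a gained chromosome in a haploid would give.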
